A study of Mus musculus with 16 samples.

How the data were processed

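ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, was run on retinal ganglion cells, the output neurons of the retina, sorted by flow cytometry from the eyes of female mice. Per the labels, experimental autoimmune encephalomyelitis (EAE), a model of inflammatory demyelination in which the optic nerve and retina can be affected, was induced at 7 to 8 weeks of age. The 16 libraries fell into 4 groups by label: naive (n = 5), presymptomatic (n = 4), disease onset (n = 3) and disease peak (n = 4). The labels do not say whether libraries came from separate animals, so p-values measure the spread between libraries, part of which may be technical. Among the label numbers of the libraries used here, 13 did not occur, and presymptomatic replicate 4 and onset replicate 3 carried the numbers 16 and 17, out of stage order.

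The deposited table gave a count and an RPKM value per library for 37255 gene intervals. The submitters' processing notes name cutadapt, HISAT2 and HTSeq, without versions. The genome build, the annotation, the treatment of duplicate reads, any shift of read ends for the transposase and the handling of reads with several alignments were not given in the sources used here. The counts deposited by the authors were whole numbers per gene interval with no scaling. The RPKM values deposited by the authors divided each count by a library total and by an interval length. The length that returned 1 constant total per library was the absolute difference between the gene's span and 2000 bp, with a largest relative deviation of 4.44e-16. The median of mean counts was 0.312 over the 401 intervals with spans of 1900 to 2100 bp, against 4.75 at 900 to 1100 bp and 3.69 at 2900 to 3100 bp. These values are those of gene bodies trimmed by 1000 bp at each end, and not of windows around transcription start sites. For genes under 2000 bp the window lay about the middle, with a length of 2000 bp less the span. Under 1000 bp that window was longer than the gene and took in flanking DNA. Genes under 2000 bp made up 7.07% of those tested. The window reached the gene's start for the 1704 tested genes under 1000 bp, and the starts of longer genes lay outside the counted interval. The design fixed before the data were examined had foreseen promoter windows, so its background measure, the share of reads at receptor promoters, was computed as the share of reads in gene intervals of olfactory and vomeronasal receptors. Starts were equal to those of GRCm38.p6 for 70.5% of the names shared with a RefSeq gene table, which held 86.8% of the names; coordinates are printed as deposited, and no build is assigned to them.

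Total reads per library, as implied by the RPKM values, ranged from 7.42 to 65.2 M (megareads), and reads in intervals from 3.71 to 30.9 M. The 13 mitochondrial intervals were kept in the tests, and nuclear reads in intervals are given separately. All per-sample columns were mapped to a library by name. Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. filterByExpr with its minimum count of 10 and minimum total of 15 on the 4 groups kept 29902 genes, and libraries were scaled by TMM. A quasi-likelihood model with a mean per group was fitted to the 16 libraries, since small groups gain from a shared estimate of the spread. The 3 comparisons with naive, the 3 between stages and an F test over the 3 contrasts with naive were adjusted by Benjamini-Hochberg, with a threshold of 0.05 and no fold threshold. CPM values are TMM-scaled counts-per-million, and log2 CPM used a prior count of 2. Fold changes are log2, with a standard error derived from the F statistic.

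A set of 30 gene lists was written before the data were examined. They covered markers of retinal ganglion cells, rods, cones, bipolar, amacrine and horizontal cells, Müller glia and astrocytes, microglia and macrophages, lymphocytes, endothelium and pericytes, pigment epithelium and oligodendrocytes. Further lists held genes of the interferon response, antigen presentation, NF-kB and cytokines, axon injury, the integrated stress response, unfolded protein and heat shock responses, immediate early genes, cell death, synapse, neuronal ion channels, oxidative phosphorylation, cytosolic ribosomal proteins, replication-cluster histones and the cell cycle. The last were reprogramming factors with DNA methylation enzymes, Hox genes, other Polycomb targets, the circadian clock and cholesterol synthesis. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 30 lists. Each library's list score was the mean log2 CPM of the tested members, compared by a two-sided exact permutation test. The density of a list was the median over its genes of reads per kb of interval and M of nuclear reads, for intervals of at least 500 bp, with its percentile among 10000 random lists of the same size matched on interval length in 20 bins. Genes under 2000 bp could thus be matched with longer genes of equal interval length, whose starts lay outside the interval.

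The rule for named genes, also fixed before the data were examined, took for each comparison with naive the 10 largest rises and the 10 largest falls past the threshold. Where none passed, it took the 5 genes with the smallest unadjusted p in each direction, with an established symbol and an average at or above the median of all tested genes, and named them as not past the threshold. For each list it took up to 4 members past the threshold, or the 2 with the smallest p. For comparisons between stages and the F test it took the 5 genes with the smallest p. Some genes taken by this rule are not reported here, and they were left out of the alternatives for named genes. Several genes belong to families of near-identical copies, such as the replication-cluster histones and the vomeronasal receptors, and their counts are uncertain where reads could align to more than 1 copy.

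The gene test was tested on simulated counts drawn from the means and library sizes of the real libraries, with 100 genes changed by each fold. The changed genes were drawn from those at or above the median abundance of the tested genes. In presymptomatic against naive 35% of 2-fold and 96% of 4-fold changes were recovered over 28909 genes, in onset 22% and 90% over 29028, and in peak 23% and 97% over 29016, with 5, 6 and 9 false calls. A 1.8-fold rise of the rod list was called in each of the 3 comparisons and no other list was called in any. Counts were drawn independently for each gene, so false list calls under variation shared between genes were not checked. When the real libraries of these comparisons were regrouped, up to 10, 10 and 9 lists were called.

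Alternatives fixed before the data were examined were median-ratio size factors, total counts, quantile normalization with limma-trend, DESeq2 1.42.0, voom with quality weights, no filter and a stricter filter of at least 1 CPM in 8 libraries and a mean of 20 counts. They also included only the libraries compared, the replicate number as a block, the receptor share of all interval reads as a covariate, leaving out libraries 16 and 17 and leaving out each library in turn. Those added after the data were seen were nuclear intervals only, genes spanning at least 3000 bp, surrogate variables from svaseq (sva 3.50.0), nuclear reads as the denominator of the receptor share, that nuclear share as a covariate, and leaving out the 3 libraries with over 0.5% of nuclear reads in receptor intervals. Correlations across the 16 libraries, and the test of the first component against stage, used 100000 permutations. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.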

Results

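Chromatin accessibility was measured by ATAC-seq in retinal ganglion cells sorted from the eyes of female mice before and during EAE. There were 5 naive libraries, 4 from presymptomatic mice, 3 from mice at disease onset and 4 from mice at disease peak. The design compares each disease stage with the naive state and the stages with each other, and the series title places the work in a study of neurons under inflammation. Each value was a count of reads over a gene interval, which for genes over 2000 bp was the gene body without its outermost 1000 bp. Signal therefore describes accessibility within genes, except that gene starts and flanking DNA entered for genes under 1000 bp. The plot of reads against gene span shows the signature of this counting.

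**Figure D1:**
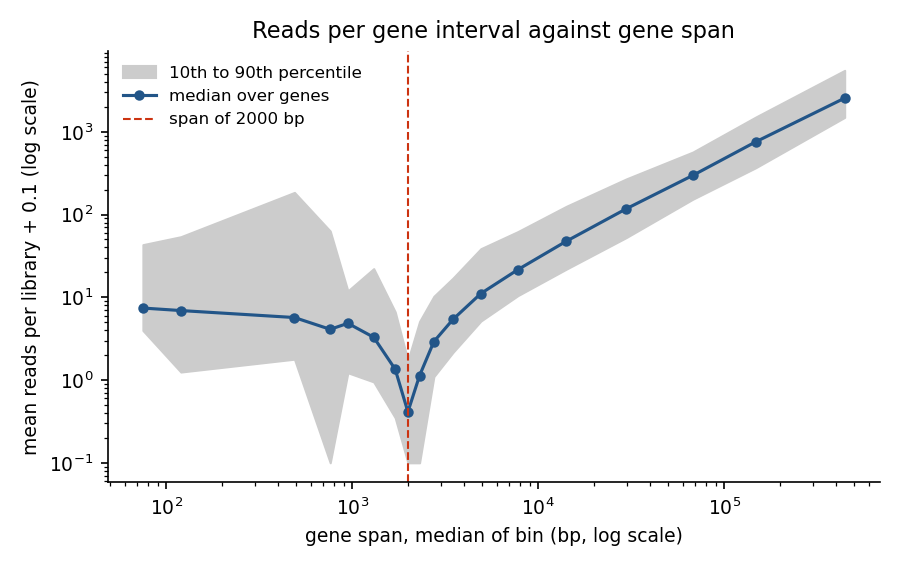
Mean reads per library plus 0.1 (y axis, log scale) against gene span in bp (x axis, log scale), with the median over genes in each bin as points and the 10th to 90th percentile of genes shaded. The median fell to 0.312 reads over the 401 genes with spans of 1900 to 2100 bp, at the dashed line, and was 4.75 for spans of 900 to 1100 bp.

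Nuclear reads in intervals, in megareads (M), were 7.92 ± 4.24 M in naive (SD, n = 5) and 6.37 ± 2.81 M in presymptomatic libraries (SD, n = 4). They were 9.70 ± 5.42 M in onset (SD, n = 3) and 3.03 ± 0.978 M in peak libraries (SD, n = 4). The peak mean minus the naive mean was −4.89 M (two-sided exact permutation p = 0.0238). The difference did not pass adjustment over the 6 tests of depth and mitochondrial share (adjusted p = 0.143). Mitochondrial genes took 52.5% ± 9.34 of interval reads in naive (SD, n = 5) and 43.1% ± 6.202 in presymptomatic libraries (SD, n = 4). They took 32.3% ± 21.9 in onset (SD, n = 3) and 53.0% ± 11.6 in peak libraries (SD, n = 4). None of these shares differed from naive beyond the spread between libraries (exact permutation p = 0.143, 0.0714 and 0.937, adjusted p = 0.286, 0.214 and 0.937). Onset replicate 3 stood apart with 8.36%, against 37.2% and 51.3% in the other onset libraries, and had the highest TMM factor, 2.02.

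Olfactory and vomeronasal receptor genes, which are expressed by sensory neurons of the nose, served as a measure of background. Their 1457 intervals took 0.162% ± 0.0668 of reads in naive (SD, n = 5) and 0.208% ± 0.0421 in presymptomatic libraries (SD, n = 4). They took 0.158% ± 0.0315 in onset (SD, n = 3) and 0.158% ± 0.0638 in peak libraries (SD, n = 4). Between 3880 and 45778 reads per library lay behind these shares. The differences from naive of 0.0460, −0.0044 and −0.0049 percentage points were within the spread between libraries (exact permutation p = 0.294, 0.982 and 0.881, adjusted p = 0.881, 0.982 and 0.982). As a share of nuclear reads, the differences were 0.00464, −0.119 and −0.0251 percentage points (exact permutation p = 0.960, 0.339 and 0.873), with 0.360% ± 0.174 in naive (SD, n = 5) and 0.241% ± 0.0419 in onset libraries (SD, n = 3). By this share, receptor genes were highest in naive replicate 3 (0.580%), naive replicate 4 (0.511%) and peak replicate 3 (0.508%).

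**Figure D2:**
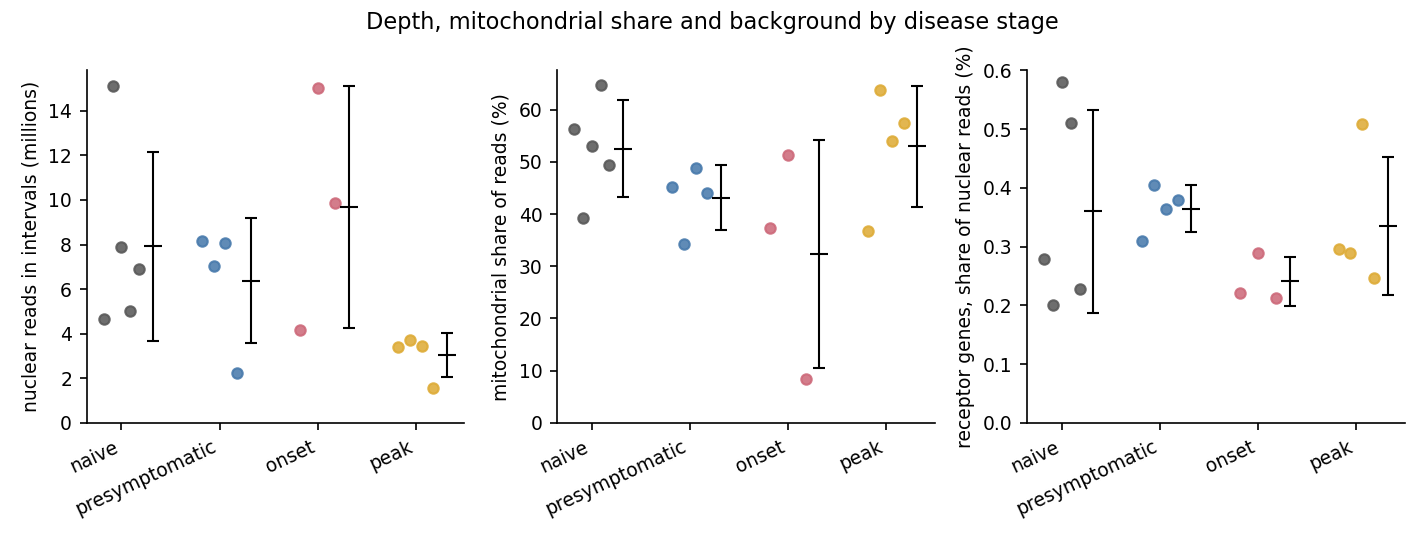
Nuclear reads in intervals in M (left), mitochondrial share of interval reads in percent (middle) and receptor gene share of nuclear reads in percent (right) for each of the 16 libraries, by stage; points are libraries and bars are the mean and SD. Peak libraries lie at 3.03 ± 0.978 M nuclear reads, onset replicate 3 at a mitochondrial share of 8.36%, and naive replicates 3 and 4 and peak replicate 3 above 0.5% on the right.

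The largest axis of variation followed the receptor share of nuclear reads. Of the 29902 genes behind this axis, 682 were receptor intervals, so axis and share were not fully separate. Whether the share measured background or another property of the libraries was not tested. The first principal component held 20.3% of the variance and rose with the log2 receptor share of nuclear reads across the 16 libraries (Pearson r = 0.956, Spearman rho = 0.909). The permutation p was 1e-05 for each, the smallest the permutations can give, and 3e-05 when adjusted over 3 relations. Without the 2 farthest libraries r was 0.938, and within stages it was 0.953. The same component was not related to mitochondrial share (r = 0.396, rho = 0.335, permutation p = 0.132 and 0.203, adjusted p = 0.198 and 0.304) or nuclear reads (r = −0.025, rho = −0.026, permutation p = 0.926 and 0.925). Differences between stages held 14.3% of the variance of this component, against a median of 17.3% when the stage labels were permuted (permutation p = 0.590, 1 test). Libraries of 1 stage correlated with each other at a median r of 0.898 across genes (range 0.834 to 0.960), and libraries of different stages at 0.904; genes are not independent replicates.

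At the presymptomatic stage, before signs of disease, markers of ganglion cells, glia and immune cells did not differ from the naive libraries beyond their spread. Ganglion cell markers had a median log2 fold change of −0.08, with 10 of 29 tested members higher. Among the members with the smallest p, the surface protein Thy1 was at 3.14 against 5.21 mean CPM in naive and the transcription factor Isl2 at 2.26 against 4.16. Microglia and macrophage markers (8 of 18 higher, median −0.16), lymphocyte markers (10 of 22, −0.04) and Müller glia and astrocyte markers (5 of 19, −0.13) did not pass the test either. Interferon response genes split in direction, with 14 of the 38 tested members higher and a list median of −0.07. Ifit1, an antiviral effector, had a log2 fold change of 1.28 ± 0.53 (SE) and Zbp1, a sensor of Z-form nucleic acids, one of −1.25 ± 0.53. None of the 30 lists passed camera (adjusted p of at least 0.851), and 0 members passed in any list when adjusted over the list alone.

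Among the genes named by rank, the first on the higher side was Fam20b, a kinase of glycosaminoglycan assembly, with 14.0005 ± 2.60 CPM (SD, n = 4) against 7.89 ± 2.21 in naive (SD, n = 5). Slc12a2, the sodium-potassium-chloride importer NKCC1, had 24.4 ± 4.79 against 15.9 ± 3.76. Their log2 fold changes were 0.81 ± 0.29 and 0.61 ± 0.24 (SE). The other named genes on this side were Dnajc21 (0.79 ± 0.32), Osgin2 (0.85 ± 0.35) and Lbp (0.85 ± 0.36), which encodes the lipopolysaccharide binding protein. On the lower side, Ankrd28 had 22.97 ± 3.67 CPM (SD, n = 4) against 37.8 ± 7.47 in naive (SD, n = 5), a log2 fold change of −0.72 ± 0.22 (SE). Samhd1, a dNTP hydrolase that restricts viruses, stood at −0.92 ± 0.30, the poly(A) polymerase gene Papolg at −0.95 ± 0.32, Itfg1 at −0.88 ± 0.28 and Lnp, a protein of endoplasmic reticulum junctions, at −0.88 ± 0.29. The cyclin gene Ccnb2, the cell cycle member with the smallest p, was at 1.32 ± 0.42. None passed the threshold (edgeR adjusted p = 1.00 for each named gene). edgeR called 0 of 29902 genes, with 332 at an unadjusted p under 0.05 against 1495.1 by chance. DESeq2, voom with quality weights and limma-trend each called 0, with 516, 1613 and 470 at an unadjusted p under 0.05.

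The other lists did not pass at this stage. Immediate early genes had a median of −0.25 (15 of 22 lower), replication-cluster histones −0.27 (17 of 21 lower) and antigen presentation genes −0.24 (13 of 19 lower). Rods stood at −0.16, cones at −0.06, bipolar cells at −0.01 and amacrine and horizontal cells at −0.00, with synapse genes at −0.10, ion channels at −0.06 and oxidative phosphorylation at −0.12. Without presymptomatic replicate 4, rod markers passed camera at a median of −0.41 (adjusted p = 8.24e-05), and without naive replicate 3 immediate early genes passed at −0.44 (adjusted p = 0.0200). Without naive replicate 4 or presymptomatic replicate 3 the histone list passed at −0.41 and −0.42 (adjusted p = 0.00106 and 0.0118). With the receptor share of all reads as a covariate it passed in the opposite direction, at 0.13 (adjusted p = 0.00390).

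At disease onset, gene bodies of rod photoreceptor genes carried more reads on average than in naive cells. All 19 tested rod markers were higher, with a median log2 fold change of 0.86, and 12 of them passed when adjusted over the list alone, although 0 passed over all genes. Prph2, the disc rim protein peripherin 2, had 44.1 ± 26.1 CPM (SD, n = 3) against 17.2 ± 6.27 in naive (SD, n = 5), a log2 fold change of 1.37 ± 0.37 (SE). Gnb1, the beta subunit of transducin that other neurons also express, had 46.6 ± 16.98 against 23.6 ± 6.31 CPM (0.98 ± 0.28), and Gnat1, the rod transducin alpha subunit, had 15.3 ± 7.73 against 7.26 ± 1.58 (1.09 ± 0.32). Esrrb, a rod nuclear receptor that also stood in the list of reprogramming factors and passed there when adjusted over the list alone, was at 0.71 ± 0.21.

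The rod list passed camera at the preset correlation (adjusted p = 9.09e-16) and not otherwise. The adjusted p was 0.348 with an estimated correlation and 0.262 with fry, and the exact permutation p of the library scores was 0.0536 (adjusted p = 0.783). The scores were 4.08, 4.10 and 4.97 log2 CPM in the 3 onset libraries and 3.27 to 4.10 in naive ones, so onset replicates 1 and 2 lay within the naive range. Onset replicate 3 had both the highest rod score and the lowest mitochondrial share, and without it the median was 0.42, still past camera (adjusted p = 2.01e-05). Cone markers did not pass, with 8 of 13 higher at a median of 0.30 (adjusted p = 0.167), among them Gucy2e, the photoreceptor guanylate cyclase, at 0.91 ± 0.31 (SE). Bipolar cell markers had 15 of 20 higher at 0.20 (adjusted p = 0.304), and amacrine and horizontal cell markers 13 of 20 at 0.03 (adjusted p = 0.390).

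**Figure D3:**
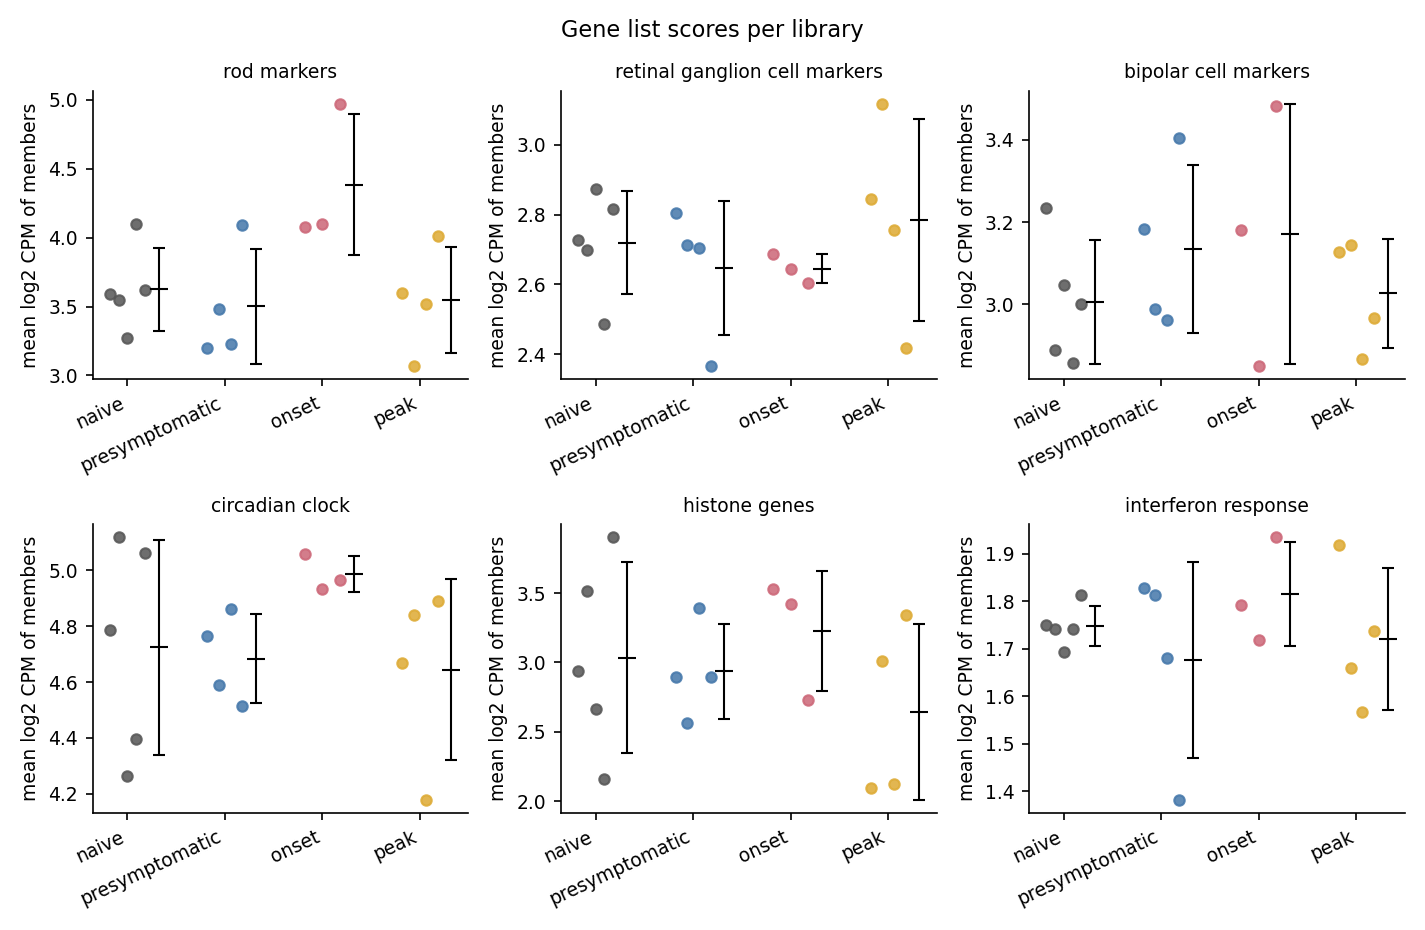
Mean log2 CPM of the tested members (y axis) for 6 gene lists in each library, by stage (x axis); points are libraries and bars are the mean and SD. Rod scores reach 4.97 in onset replicate 3 and 4.08 and 4.10 in the other onset libraries, against 3.27 to 4.10 in naive ones, while ganglion cell scores overlap between all stages.

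Ganglion cell markers themselves were close to their naive level at onset (13 of 29 higher, median −0.06, adjusted p = 0.432). An exception by size was Slc17a6, the vesicular glutamate transporter of ganglion cells, with 9.85 against 17.7 mean CPM (−0.84 ± 0.29, SE), not past the threshold over the list alone. Circadian clock genes passed the preset camera test with 16 of 20 higher and a median of 0.22 (adjusted p = 0.0147), led by Per1 (0.72 ± 0.30) and the nuclear receptor Nr1d1 (0.59 ± 0.29). The adjusted p was 0.683 with an estimated correlation, and 0 members passed when adjusted over the list alone. That median was −0.03 with the nuclear receptor share as a covariate, −0.03 without the 3 libraries of highest receptor share and −0.01 with surrogate variables, and the list did not pass without naive replicate 3 (0.09), naive replicate 4 (0.10) or onset replicate 1 (0.15).

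No list of injury or inflammation passed at onset, and their directions were mixed. Axon injury genes had 15 of 25 higher at a median of 0.15 (adjusted p = 0.304), including Map3k12, the DLK kinase of axon damage signalling (0.78 ± 0.32, SE). NF-kB and cytokine genes had 15 of 23 higher at 0.08, with the NF-kB inhibitor Tnfaip3 at 0.68 ± 0.31. The integrated stress response had 15 of 20 higher at 0.16, the unfolded protein and heat shock response 11 of 18 at 0.04 and cytosolic ribosomal proteins 14 of 21 at 0.20 (adjusted p = 0.0941). The interferon response (23 of 38, 0.02), antigen presentation (9 of 19, −0.04), lymphocyte (11 of 22, 0.02) and microglia and macrophage lists (7 of 18, −0.23, adjusted p = 0.517) did not pass. Cell death genes had 11 of 27 higher at −0.02, with Aifm1, the mitochondrial apoptosis-inducing factor, at −0.96 ± 0.37, and the Polycomb targets outside the Hox clusters 16 of 48 at −0.22 (adjusted p = 0.304). Without onset replicate 3 the number of lists past camera went from 2 to 6, adding amacrine and horizontal cells (0.14), axon injury (0.20), histones (0.36) and Hox genes (−0.68). It was 4 without naive replicate 5, with histones (0.27) and ribosomal proteins (0.37), and 3 without naive replicate 2, with ribosomal proteins (0.30), or onset replicate 2, with bipolar cells (0.38). The histone list passed in the opposite direction with surrogate variables (−0.17, adjusted p = 0.0258) and without the 3 libraries of highest receptor share (−0.22, adjusted p = 0.0311).

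Of the genes named by rank at onset, those on the higher side were mostly photoreceptor genes. They were Rp1l1, a protein of the photoreceptor axoneme (1.16 ± 0.31, SE), Prph2, Mpp4, a scaffold of photoreceptor synapses (0.98 ± 0.28), and Gnb1, joined by the inositol phosphate kinase gene Ip6k2 (1.14 ± 0.34). Those on the lower side were Chm, a Rab escort protein (−1.05 ± 0.30), Serpini2 (−1.34 ± 0.39), the liver cytochrome Cyp3a11 (−1.41 ± 0.41), the collectin Colec10 (−0.92 ± 0.27) and Vmn2r67 (−1.60 ± 0.48). Vmn2r67 is itself 1 of the vomeronasal receptors that measured background. The smallest edgeR adjusted p was 0.985, so 0 of 29902 genes passed, with 1343 at an unadjusted p under 0.05 (467 higher and 876 lower). DESeq2, voom with quality weights and limma-trend also called 0, with 1834, 1676 and 1243. Scaling by total counts, which include mitochondrial reads, shifted the median gene by 0.60 in this comparison, against −0.01 with TMM, and the fold changes given here are relative to the TMM scale.

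At disease peak, the rod median was close to its naive value. Rod markers had 8 of 19 higher at a median log2 fold change of −0.03 (adjusted p = 0.855), and cones 6 of 13 at −0.01. Kcne2, a potassium channel subunit in the cone list, was at −2.51 ± 0.75 (SE) and passed when adjusted over the list alone, with 0.54 against 2.48 mean CPM. Ganglion cell markers leaned higher, with 21 of 29 above naive at 0.16 (adjusted p = 0.375), among them the transcription factor Isl1 (0.65 ± 0.40) and the melanopsin gene Opn4 (0.57 ± 0.45). Müller glia and astrocyte markers leaned lower, with 13 of 19 below naive at −0.25 (adjusted p = 0.111), including Glul, glutamine synthetase (−0.89 ± 0.40), and Clu, clusterin (−0.92 ± 0.38). They passed at −0.30 without naive replicate 3 (adjusted p = 0.0338) or peak replicate 4 (adjusted p = 0.0322).

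The replication-cluster histone genes, which encode the core and linker histones, were the 1 list past camera at peak: all 21 tested members were lower, at a median of −0.49 (adjusted p = 0.00160). The linker histone gene Hist1h1e was at −0.94 ± 0.38 (SE) and Hist1h4c at −0.57 ± 0.37, and 0 of 21 passed over the list alone. The call was lost with an estimated correlation (adjusted p = 0.965), with fry (adjusted p = 0.948) and in the library scores (exact permutation p = 0.405). It was also lost with surrogate variables (−0.17) and with the replicate block. The same held without naive replicate 2 (−0.39), naive replicate 5 (−0.18), peak replicate 1 (−0.30) or peak replicate 3 (−0.26).

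Hox genes had 12 of 15 higher at peak with a median of 0.29 (adjusted p = 0.0677), led by Hoxc6 (1.30 ± 0.59, SE) and Hoxc13 (1.65 ± 0.76), and passed without naive replicate 1 (0.47), peak replicate 4 (0.34) or libraries 16 and 17 (0.26), and with the stricter filter (0.44). Cytosolic ribosomal proteins had 16 of 21 higher at 0.31 (adjusted p = 0.375) and oxidative phosphorylation 23 of 32 at 0.11. Immune lists did not pass: the interferon response had 21 of 38 higher at 0.02, antigen presentation 8 of 19 at −0.05 and microglia and macrophages 9 of 18 at −0.03. Lymphocytes had 8 of 22 higher at −0.12 and NF-kB and cytokine genes 10 of 23 at −0.06, although the costimulatory receptor gene Cd40 was at 1.21 ± 0.43. Immediate early genes had 15 of 22 lower at −0.24, with Egr2 at −0.55 ± 0.26 and Fosb at −0.84 ± 0.41, and passed without naive replicate 3 (−0.38). Axon injury genes had 14 of 25 lower at −0.04, with Jun at −0.53 ± 0.32. Reprogramming factors and DNA methylation enzymes had 13 of 17 lower at −0.18, among them the DNA methyltransferases Dnmt3a (−0.37 ± 0.23) and Dnmt3b (−0.46 ± 0.28). The remaining lists stood at medians of −0.16 to 0.16: endothelium and pericytes 0.16, cholesterol synthesis 0.06, cell death 0.02, cell cycle −0.00, oligodendrocytes −0.02, circadian clock −0.02, neuronal ion channels −0.04 and Polycomb targets −0.04. Below these were bipolar cells −0.05, integrated stress response −0.10, amacrine and horizontal cells −0.11, pigment epithelium −0.11, synapse −0.14 and unfolded protein response −0.16.

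**Figure D4:**
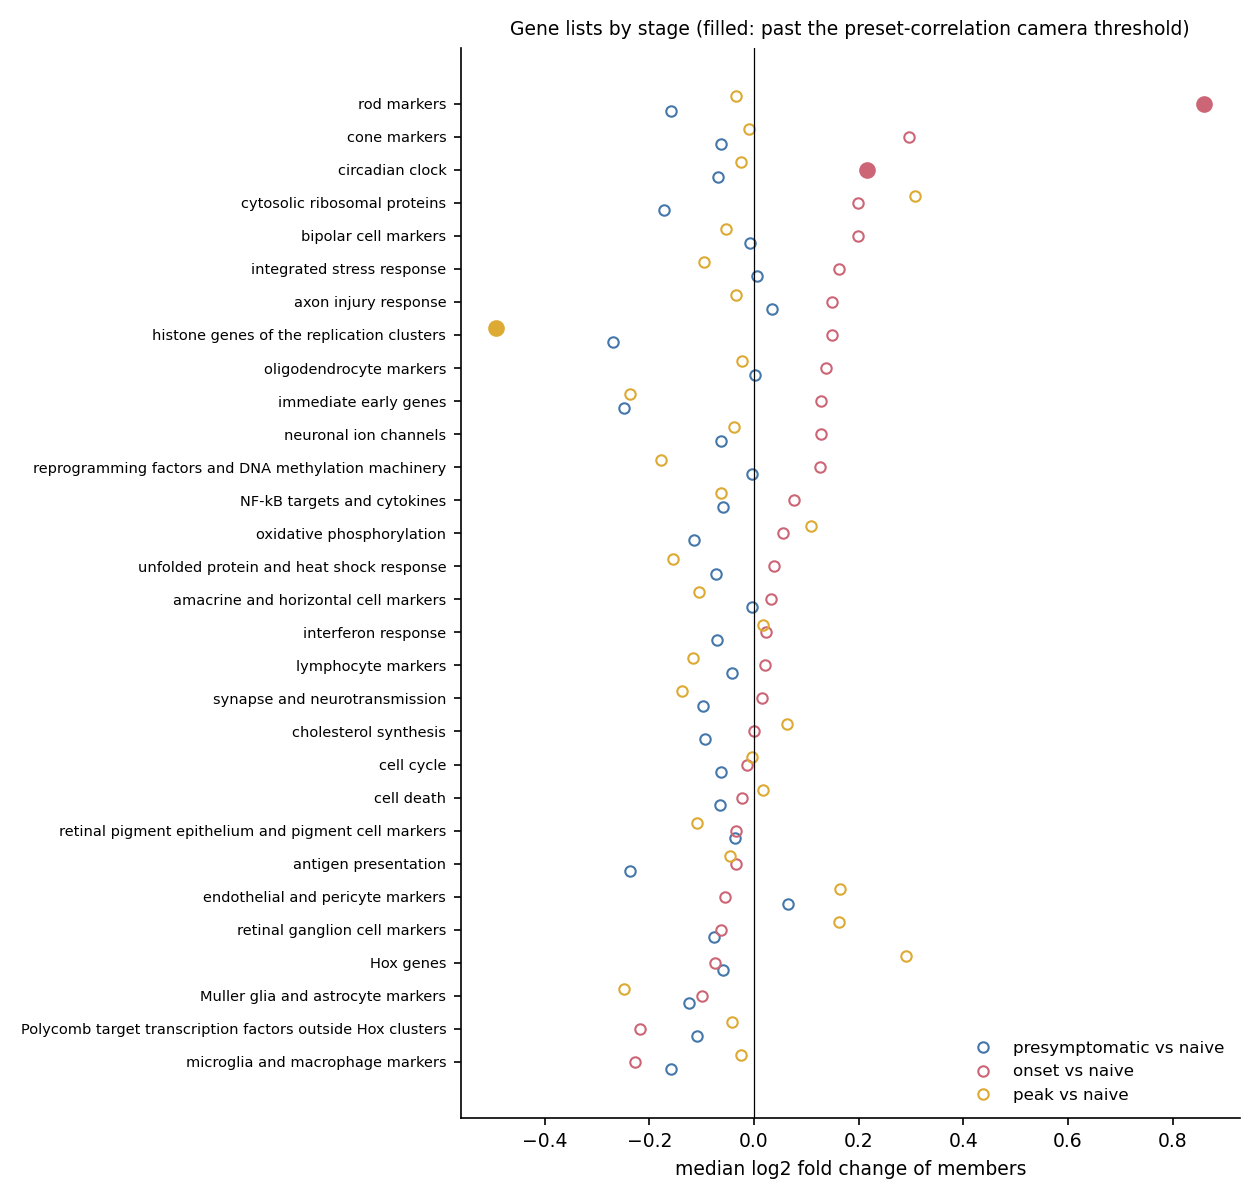
Median log2 fold change of the tested members (x axis) of each of the 30 gene lists (y axis) at the presymptomatic stage, onset and peak against naive; filled points passed camera at the preset correlation. The filled points are rods (0.86) and the circadian clock (0.22) at onset and histones (−0.49) at peak, and each of these calls is lost with an estimated correlation.

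The genes named by rank at peak were headed by D6Ertd474e, with 20.2 ± 4.71 CPM (SD, n = 4) against 9.66 ± 0.836 in naive (SD, n = 5), at chromosome 6 from 143245888 to 143297879 in the deposited coordinates. Its log2 fold change was 1.06 ± 0.24 (SE), and it passed in DESeq2 (1.07, adjusted p = 0.0365) and not in edgeR (adjusted p = 1.00). Cttn, the actin-binding protein cortactin (1.19 ± 0.30), the mitochondrial carbonic anhydrase gene Car5a (1.04 ± 0.29), Prkra, an activator of the kinase PKR (0.82 ± 0.26), and the inflammasome sensor gene Naip2 (0.82 ± 0.26) followed. On the lower side, Adh5, which removes formaldehyde and S-nitrosoglutathione, had 15.97 ± 2.63 CPM (SD, n = 4) against 28.3 ± 8.29 in naive (SD, n = 5), a log2 fold change of −0.82 ± 0.23 (SE). Prx, the myelin protein periaxin, was at −0.98 ± 0.29, the prostaglandin D2 receptor gene Ptgdr2 at −1.20 ± 0.35, the pro-apoptotic gene Pawr at −0.82 ± 0.26 and Tnks2, a tankyrase, at −0.77 ± 0.25. edgeR called 0 of 29902 genes, with 1055 at an unadjusted p under 0.05 (528 higher and 527 lower). DESeq2 called 1, with 1373 at an unadjusted p under 0.05, and voom with quality weights and limma-trend each 0, with 941 and 1171.

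Between stages, rod markers were on average highest at onset, although the scores of presymptomatic replicate 4 (4.09) and peak replicate 4 (4.01) were close to those of onset replicates 1 and 2. Rod markers were higher at onset than at the presymptomatic stage (18 of 19, median log2 fold change 1.18, camera adjusted p = 3.80e-18, 11 past the threshold when adjusted over the list alone). They were lower at peak than at onset (18 of 19, −0.81, adjusted p = 1.33e-12, 9 past it over the list alone). With an estimated correlation the adjusted p was 0.224 and 0.420. Gnat1 had 15.3 ± 7.73 CPM at onset (SD, n = 3) against 5.26 ± 0.856 at the presymptomatic stage (SD, n = 4), a log2 fold change of 1.56 ± 0.35 (SE), and Gnb1 was at 1.251 ± 0.30. Of the 30 lists, 5 passed camera from presymptomatic to onset, the others being the circadian clock (0.27), immediate early genes (0.40), cones (0.23) and histones (0.34), and 3 from onset to peak, with the clock (−0.27) and histones (−0.48). The adjusted p of these others was 0.236 for cones and 0.610 to 0.684 for the rest with an estimated correlation, and 0 of their members passed over the list alone. The 3 onset libraries had lower nuclear receptor shares (0.212% to 0.289%) than the 4 presymptomatic ones (0.310% to 0.405%), so this contrast ran along the axis of the receptor share. With the nuclear receptor share as a covariate the rod medians were 1.06 from presymptomatic to onset and −0.95 from onset to peak (adjusted p = 3.79e-22 and 3.16e-14). The clock medians fell to −0.01 and −0.10 and the histone medians were −0.20 and −0.19, and neither list passed (adjusted p of 0.109 to 0.906). No list passed between presymptomatic and peak, where with this covariate the histone list passed at −0.37 (adjusted p = 0.000406).

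The gene with the smallest adjusted p of any comparison among those named was Adh5, at 15.97 ± 2.63 CPM at peak (SD, n = 4) against 40.2 ± 0.489 at onset (SD, n = 3). Its log2 fold change was −1.33 ± 0.26 (SE), with an edgeR adjusted p of 0.190. DESeq2 called it (−1.28, adjusted p = 0.00430). Adh5 lay at chromosome 3 from 138437200 to 138455499 and was also lower at peak than at the presymptomatic stage by a log2 fold change of −0.86 ± 0.24. Prx (−1.39 ± 0.32), the cytokine gene Mif (−1.39 ± 0.33), C2cd2l (−1.85 ± 0.47) and Rp1l1 (−1.29 ± 0.33) were the other genes named from onset to peak. From presymptomatic to onset these were Tob2 (1.246 ± 0.32), Rnaseh2a (1.22 ± 0.32) and Cfap70 (1.05 ± 0.28). From presymptomatic to peak they were Ddx4 (1.23 ± 0.29), Fam118a (1.17 ± 0.30), the nuclear import gene Kpna3 (1.08 ± 0.29) and Polr1b (1.44 ± 0.40). edgeR called 0 genes in each of the 3 comparisons, with 1181, 1969 and 1019 at an unadjusted p under 0.05 in the order presymptomatic to onset, onset to peak and presymptomatic to peak. DESeq2 called 1, 5 and 0, and voom with quality weights and limma-trend each 0.

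**Figure D5:**
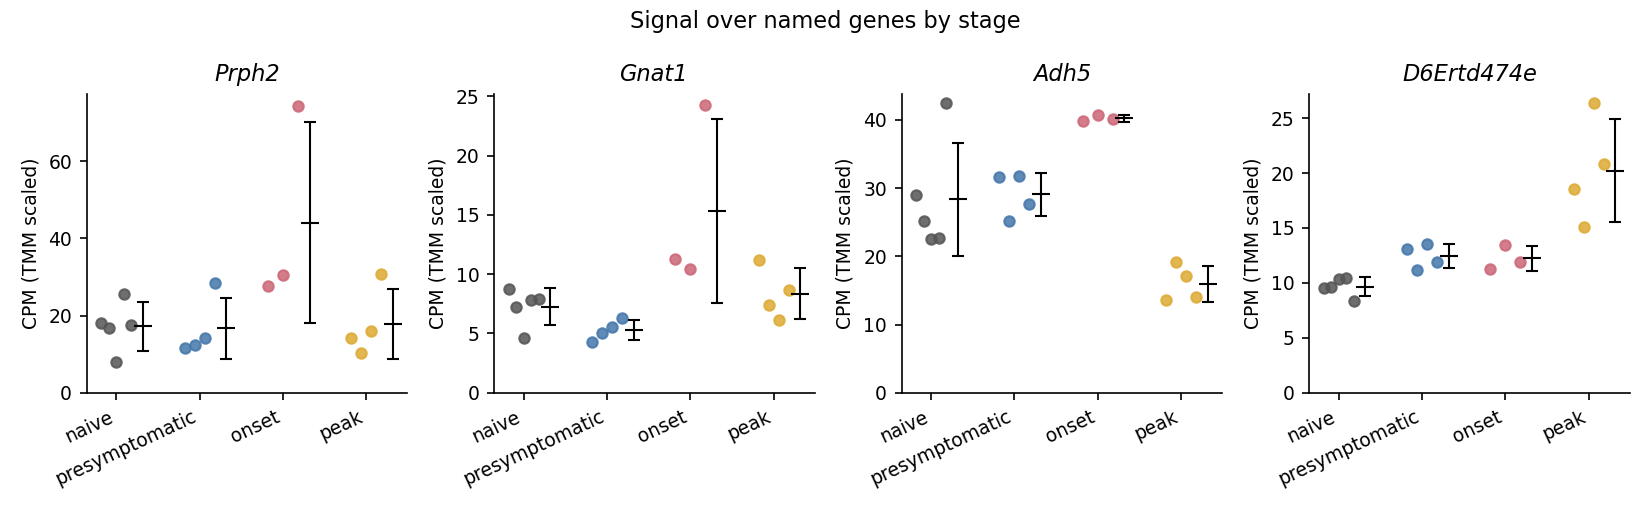
TMM-scaled CPM (y axis) of Prph2, Gnat1, Adh5 and D6Ertd474e in each library, by stage (x axis); points are libraries and bars are the mean and SD. Prph2 and Gnat1 are highest at onset (44.1 ± 26.1 and 15.3 ± 7.73), Adh5 is lowest at peak (15.97 ± 2.63) and D6Ertd474e is highest at peak (20.2 ± 4.71).

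The F test over the 3 stages against naive also called 0 genes in edgeR (smallest adjusted p = 1.00), with 927 at an unadjusted p under 0.05. DESeq2 called 5, with 1408, while voom with quality weights and limma-trend each called 0. The genes named for it, the first by p among those with an established symbol and an average at or above the median, were Adh5, Gnb1, Gnat1, Rp1l1 and D6Ertd474e. The median standard error of a log2 fold change was 0.39 at the presymptomatic stage, 0.42 at onset and 0.40 at peak. In simulated counts at this depth and number of libraries, 35%, 22% and 23% of 2-fold changes in single genes were recovered in these comparisons, and 96%, 90% and 97% of 4-fold changes. The changed genes were at or above the median abundance, so recovery in less abundant genes was not measured. The simulated counts held no variation shared between genes, so recovery in the real libraries may differ.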

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

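The tests of a single onset library and of a lower share of ganglion cells were chosen only after the rod result was seen, as were the surrogate variables, the nuclear receptor share as a covariate and the exclusion of the 3 libraries with the highest receptor share. Both tests of genes under 1000 bp, the splits for the strongest list, for unadjusted p and for lists between stages were also chosen after results were seen. The others were chosen before their results were seen.

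Rod markers had a median log2 fold change of 1.18 from presymptomatic to onset and −0.81 from onset to peak, each past a camera test of that difference at the preset correlation but not with an estimated one (adjusted p = 0.224 and 0.420). Without onset replicate 3 the median against naive was 0.42 (0.420, against 0.861 with it) and still past camera at the preset correlation, while the scores of onset replicates 1 and 2 (4.08 and 4.10) lay within the naive range, so this 1 library may account for much of the pattern. Libraries 16 and 17, presymptomatic replicate 4 and onset replicate 3, had the highest rod scores of their groups (4.09 and 4.97). Presymptomatic replicates 1 to 3 against replicate 4 and the onset libraries gave a rod median of −1.21, against the real 1.18 for onset. Without both, the onset median against naive was 0.42 (camera adjusted p = 1.31e-05). The labels do not say what these numbers stand for, so a property shared by the 2 libraries stays open. A lower share of ganglion cells that let in the other retinal neurons in equal measure would raise their markers alike. The pooled median of bipolar, amacrine and horizontal cell markers was 0.0959, which argues against that case only. It cannot speak to a lower share made up mainly by rods. Of 29 tested photoreceptor genes held out of the rod list, 25 were higher at onset, with a median of 0.651 (camera adjusted p = 9.64e-09, 0.155 with an estimated correlation, exact permutation p of the library scores = 0.0357), so rod cells or their chromatin passing the ganglion cell sort may be the source, and the abundant rod gene Sag (46.1 against 25.5 mean CPM) moved with them. Without onset replicate 3 the held-out median was 0.329 (exact permutation p = 0.143, where 0.0476 is the smallest possible), and whether disease at onset changes rod contamination or ganglion cell chromatin remained untested.

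Histone genes of the replication clusters differed between onset and peak, at −0.48 by a camera test of the difference at the preset correlation but not with an estimated one (adjusted p = 0.610), and stood at −0.49 at peak against naive. With the receptor share of all reads or of nuclear reads as a covariate the peak median was −0.530 or −0.478. The mean log2 nuclear share differed by only −0.029 between peak and naive, so these fits had little to adjust. They argue only against a difference in mean receptor share, not against other structure of the libraries. With surrogate variables the peak median was −0.17 and the call was lost, as it was with the replicate block. From onset to peak the median fell to −0.19 with the nuclear share (camera adjusted p = 0.109). Other genes under 1000 bp, whose intervals take in their starts, with a density in presymptomatic and onset libraries of at least the lower quartile of the histone genes (6.75 reads per kb and M of nuclear reads), had a median of −0.303 ± 0.0239 (SE over genes) at peak, lower in 175 of 210. This SE treats genes of the same libraries as independent and holds no spread between libraries, and the drop was not tested between libraries. A weaker signal at open starts of short genes may account for part of the histone result. Of 100 splits of the naive and peak libraries, 26 gave an absolute histone median as large as the real −0.493, the highest other being 0.974, so chance cannot be excluded. A change of histone gene accessibility with disease stays open and was not tested apart from this.

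The absence of called genes was weighed against hidden structure and against the intervals. With 4 surrogate variables, at most 0 genes passed in the comparisons with naive in edgeR, short of the 10 predicted if hidden variation masked changes. At an unadjusted p under 0.05 there were 1043, 1306 and 2373 genes at presymptomatic, onset and peak, against 332, 1343 and 1055 without them. The F test called genes in this fit, among them Sag and Rgs9bp. This fit left 8 residual degrees of freedom against 12, and its recovery was not simulated. The absence of calls therefore cannot exclude that such variation hides changed genes. Among the 1704 tested genes under 1000 bp, whose intervals take in their starts, 0 passed in edgeR in each comparison when adjusted over these alone, and 0.998%, 3.35% and 4.46% had an unadjusted p under 0.05. At peak, however, the short genes of high density were lower in 175 of 210, with a median log2 fold change of −0.303 that was not tested between libraries. Recovery was not simulated for short genes. The absence of calls among them therefore cannot decide whether the loss of gene starts from the intervals is the reason. Stage effects of about 2-fold and below stay open, since 22% to 35% of 2-fold changes were recovered in simulated counts. The changed genes there were at or above the median abundance, and recovery in less abundant genes was not simulated. The simulated counts also held no variation shared between genes, so these rates may not hold for the real libraries and do not rule out larger changes.

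The real count of called genes was 0 in each comparison, so every split gave at least as many and the count of splits says nothing about chance. These were 100 of 100 splits at the presymptomatic stage (highest other 0) and 56 of 56 at onset (highest other 1479). They were 100 of 100 at peak (highest other 2151) and 100 of 100 for the F test (highest other 1937). Between stages these were 35 of 35 from presymptomatic to onset (highest other 0), 35 of 35 from onset to peak (highest other 3) and 35 of 35 from presymptomatic to peak (highest other 0). The splits with 1479 and 2151 genes set naive replicates 3 and 4 with onset replicate 2, and naive replicates 1, 3 and 4 with peak replicate 3, against the rest. Their differences in log2 receptor share, 0.957 and 0.861, were each the largest among the splits of that comparison, and point to a structure of the samples that follows this share. Stage was not free of it: the real difference was −0.605 from presymptomatic to onset, the largest of its 35 splits, and −0.459 at onset against naive. By the number of genes at an unadjusted p under 0.05, 99 of 100 splits gave as many as the real 332 at the presymptomatic stage (highest other 5010), 25 of 56 the real 1343 at onset (highest other 6193) and 70 of 100 the real 1055 at peak (highest other 6545), so chance cannot be excluded. For called lists at the presymptomatic stage the real count was again 0, which 100 of 100 splits had to reach (highest other 10). Of the splits, 38 of 56 gave at least the real 2 lists at onset (highest other 10) and 72 of 100 the real 1 at peak (highest other 9), so chance cannot be excluded. For the rod median at onset, 1 of 56 splits, the real one, gave 0.861, the highest other being 0.817. Since the list was the strongest of 30, the smallest camera p over all lists was also compared, and 2 of 56 splits gave one as small as the real 3.03e-17 (smallest other 2.01e-17, also of the rod list). Both counts were under 0.05 as shares of the splits of this comparison, with no allowance for the 3 comparisons with naive. The splits with 0.817 and with 2.01e-17 both kept onset replicate 3 in the stage group. The permutation of the library scores was not under 0.05 (p = 0.0536, adjusted p = 0.783), so chance was not excluded. For the clock median 21 of 56 splits gave the real 0.216 or more (highest other 0.561), so chance cannot be excluded. Between stages, 2 of 35 splits gave a rod median as large as the real 1.18 from presymptomatic to onset (highest other 1.21) and 2 of 35 the real −0.81 from onset to peak (highest other 0.830). For the clock these were 3 of 35 (real 0.27, highest other 0.341) and 5 of 35 (real −0.27, highest other 0.317), and for histones from onset to peak 10 of 35 (real −0.48, highest other 0.942), so chance cannot be excluded for any of these 5 medians.

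Circadian clock genes differed from presymptomatic to onset by a median of 0.27 and from onset to peak by −0.27, each past a camera test of that difference, though not with an estimated correlation (adjusted p = 0.684 and 0.610). The log2 nuclear receptor share differed by −0.605 and 0.431 in these comparisons, and with it as a covariate the medians were −0.01 and −0.10 (adjusted p = 0.906 and 0.511). Against naive the median at onset was −0.032 with this covariate and 0.26 with the share of all reads, which include mitochondrial ones, so the background of the libraries may account for the clock differences.

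Single libraries lay far from the rest of their group in 16 of 141 tests within the naive, presymptomatic and peak groups, where about 1 in 20 would by chance. The onset libraries were not tested in this way, so these tests do not speak to onset replicate 3. The log2 CPM values of this paragraph used no prior count. Peak replicate 4 had 1.58 M nuclear reads against 3.39 M in the nearest peak library. In log2 CPM, presymptomatic replicate 4 was high for Dnajc21 (4.18), Osgin2 (5.21) and Prkra (3.85), presymptomatic replicate 1 was high for Samhd1 (3.20) and low for Lnp (3.34), and presymptomatic replicate 3 was low for Ddx4 (2.60) and Fam118a (3.22). Among naive libraries, replicate 4 was low for Fam20b (2.04) and high for Ddx4 (4.00), and replicate 3 was low for Cttn (2.13) and C2cd2l (0.29). Among peak libraries, replicate 3 was high for Lnp (4.46) and low for Tob2 (2.82), replicate 1 was low for Colec10 (4.03) and replicate 2 was high for Ptgdr2 (2.44).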

How the results depend on the processing

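Tests with surrogate variables, nuclear intervals, genes of at least 3000 bp, nuclear denominators and without the 3 libraries of highest receptor share, the nuclear share as a covariate, and all alternatives for single lists, were chosen only after results were seen. The cause of each difference was not tested, except where fewer libraries or genes entered. At presymptomatic and onset against naive, 0 genes passed under each of 25 and 24 alternatives, with 232 to 2266 and 591 to 5161 at an unadjusted p under 0.05. At peak DESeq2 called 1 (D6Ertd474e). From presymptomatic to onset DESeq2 called 1 (XR_001779364.1), the replicate block 1 and surrogate variables 4 (among them Sag, Rgs9bp and Prph2). From onset to peak DESeq2 called 5 (Adh5, Nrl, Zfp263, Gm41702, Emd) and surrogate variables 1. From presymptomatic to peak 1 passed without the 3 libraries of highest receptor share (Gm9257). For the F test these were 2 with total counts (among them Prph2), 5 with DESeq2 (Adh5, Gm32080, Nrl, Gm41702, Emd), 3 with surrogate variables (among them Sag and Rgs9bp) and 1 without the 3 libraries (Gm9257). These genes were named after their values were seen.

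Lists past camera at presymptomatic numbered 2 with the receptor covariate, 1 without libraries 16 and 17 (rods, −0.40), 0 to 1 leaving out 1 library each, 1 with surrogate variables (rods, −0.27) and 3 without the 3 libraries of highest receptor share. At onset, where 2 passed, they numbered 3 with the stricter filter (adding ribosomal proteins), 4 with the replicate block, 7 without libraries 16 and 17, 1 to 6 leaving out 1 library each, 3 with surrogate variables (rods, with glia and histones lower), 3 with the nuclear share as a covariate (rods and cones, with glia lower), 4 without the 3 libraries, and 0 with an estimated correlation or fry. At peak, where 1 passed, they numbered 2 with the stricter filter, 0 with the replicate block, 2 without libraries 16 and 17, 0 to 3 leaving out 1 library each, and 0 with genes of at least 3000 bp. They numbered 0 with surrogate variables, 3 without the 3 libraries, and 0 with an estimated correlation or fry.

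The rod median at onset kept its direction in all 21 alternatives and its call in 19 (0.42 to 1.02); 0.86 was not called with an estimated correlation or fry. The clock median at onset was 0.086 to 0.36 leaving out 1 library each, reversed to −0.0053 with surrogate variables, −0.029 without the 3 libraries and −0.032 with the nuclear share as a covariate, and at 0.22 was not called with an estimated correlation or fry. The histone median at peak was −0.67 to −0.18 leaving out 1 library each, and lost its call with the replicate block (−0.18), surrogate variables (−0.17), and an estimated correlation or fry (−0.49). The receptor share difference, never past its test, was reversed at onset with olfactory receptors alone (0.00181), was −0.119 with nuclear reads as the denominator, and ranged from −0.0226 to 0.0231 leaving out 1 library each; at peak that range was −0.0303 to 0.0225. Of 3381 alternative values of 217 pairs of a named gene and a comparison, 5 reversed and 2 passed (D6Ertd474e and Adh5 in DESeq2). At presymptomatic, Hist1h4a (−0.41) reversed to 0.077 with the receptor covariate. Dusp5 at onset (0.50) reversed to −0.012 with voom and −0.17 without libraries 16 and 17, and leaving out 1 library each it was −0.18 to 0.82. Foxp3 at peak (0.74) was −0.23 to 0.99 leaving out 1 library each, lowest without peak replicate 3.

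Replicate numbers did not pair the libraries. Over 21 pairs with equal numbers, deviations from the group means correlated at a mean r of −0.013, 6 pairs exceeded 0.1, and 2 of 16 libraries correlated best with their own number, so the block fits share only a number. The median standard error of a log2 fold change was 0.40 at peak, with 1.58 to 3.702 M nuclear reads per library, against 0.39 at presymptomatic and 0.42 at onset, and what depth limits was not tested.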

Other observations

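The densities below were described after the data were seen, for lists fixed before. In naive libraries, reads per kb of interval and M of nuclear reads were higher over cell type genes of the retina than over most genes. Ganglion cell markers had a median density of 0.931 ± 0.0948 (SD, n = 5), above 99.95% of random lists matched on interval length, against 0.586 ± 0.0535 over all intervals. Amacrine and horizontal cell markers reached 1.24 ± 0.227, Müller glia and astrocyte markers 0.944 ± 0.108 and rod markers 0.849 ± 0.136 (99.88th percentile). Bipolar cell markers stood at 0.689 ± 0.0679 (89.74th percentile). Pigment epithelium markers stood at 0.850 ± 0.0570 (98.36th percentile) and cone markers at 0.826 ± 0.0970 (92.09th percentile). Microglia and macrophage markers were at 0.457 ± 0.0849 (6.44th percentile) and lymphocyte markers at 0.555 ± 0.0424 (14.83rd percentile).

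The densest list was that of the replication-cluster histones, at 10.5 ± 4.57 (SD, n = 5), of whose 22 genes 19 are under 1000 bp and counted with their starts. Immediate early genes, which neurons switch on with activity, had 2.03 ± 0.862, and circadian clock genes 1.28 ± 0.388. Axon injury genes were at 0.920 ± 0.148 (98.36th percentile). Hox genes, silenced by Polycomb outside the posterior body axis, had the lowest density at 0.292 ± 0.112 (0.33rd percentile), whereas Polycomb targets outside the Hox clusters, which include transcription factors used in the eye, stood at 0.580 ± 0.0577 (76.26th percentile). At peak the mean densities were 1.02 ± 0.157 for ganglion cell markers, 8.33 ± 3.07 for histones and 0.378 ± 0.173 for Hox genes (SD, n = 4), with no test of these values apart from those of the lists. Rod markers, at 0.849 in naive libraries, were at 1.03 ± 0.258 at the presymptomatic stage (SD, n = 4), 1.75 ± 0.836 at onset (SD, n = 3) and 1.07 ± 0.332 at peak (SD, n = 4). By this measure, the group mean of each library's median over genes, they lay above naive at each stage. The medians of the per-gene log2 fold changes were −0.16 at the presymptomatic stage and −0.03 at peak. The mean log2 CPM scores were 3.50 and 3.55 there, against 3.62 in naive libraries. These measures differ in the statistic as well as in the scale, and the cause of the difference was not tested.

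Among the photoreceptor genes held out of the rod list, written down before they were measured, those with the smallest p at onset were Reep6 (log2 fold change 1.34 ± 0.46, SE), Unc119 (0.93 ± 0.36), Aipl1 (1.08 ± 0.43) and Rdh12 (1.06 ± 0.43). None passed when adjusted over the list alone. The 4 members that were lower at onset included Gucy2f (−0.68 ± 0.33), so the direction was not shared by all photoreceptor genes. The median of the held-out genes was −0.17 at the presymptomatic stage and −0.11 at peak against naive, 0.74 from presymptomatic to onset and −0.74 from onset to peak.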
